A study of Arabidopsis thaliana with 87 samples.

How the data were processed

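The values were gene counts deposited by the submitters for 87 libraries of Arabidopsis thaliana Col-0 leaf, as a table of 32744 genes. Per the labels, RNA was taken up in Nucleozol and cleaned on Macherey-Nagel columns, and libraries came from 500 ng with a stranded total RNA kit and plant ribosomal RNA removal, in reduced reaction volumes. Per the submitters' notes, reads were mapped to TAIR10 and their own tests used R 4.5.1 and edgeR 4.6.3. The aligner, the strand setting and the handling of reads with several matches are not given in the sources used here. Genes were therefore named by locus, without coordinates, because the reference at hand is TAIR10.1, and near-identical copies (defensin, LHCB1, Rubisco small subunit, SAUR and HSP17 genes) were read with caution. Of the identifiers, 32548 matched that reference and the other 196 were 133 chloroplast and 63 mitochondrial loci.

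Groups were ambient or elevated CO2 (1000 ppm) at 22 °C or 30 °C, with 22, 22, 22 and 21 libraries, the group under both treatments lacking replicate 26. Labels conflict on age, with 21 days in one field and 28 in another, and on warming, where one field speaks of 30 h of light (16 h at 22 °C) and the design text of 30 h at 30 °C. The hour of harvest is not given, so time of day cannot be held apart from treatment. Replicate numbers 5 to 12, 14 to 16 and 18 to 28 each stand for 1 batch date shared by all groups, and dates fell into 6 weeks. The labels do not tell whether replicates are separate plants, pools or repeated growth, so p-values measure the spread between libraries, which may be partly technical. Small RNA, protein, metabolite and fluorescence data of the same plants were not analysed here.

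Residual log CPM of libraries with the same number correlated at 0.197 on average (129 pairs), against 0.0721 for the same week (351 pairs) and -0.0205 for other weeks (2358 pairs), so numbers pair the libraries. The replicate block was run as an alternative to the unblocked test fixed in the design. Within groups no library was a copy of another, since the least difference between any pair was a chi-square of 17.0 per degree of freedom.

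Design, tests, gene lists, the rule for named genes and most alternatives were fixed before the data were examined. Genes with too few counts were removed with filterByExpr, which left 19589 tested, 13155 not tested and, among the latter, 3637 at 0 in every library. TMM factors and edgeR's quasi-likelihood test with 1 mean per group over all 87 libraries gave 6 comparisons: warming at ambient and at elevated CO2, CO2 at 22 °C and at 30 °C, both treatments against control, and the interaction. Benjamini-Hochberg adjustment ran over all tested genes of a comparison, with 0.05 as threshold. The standard error was the log2 ratio over the root of F. Counts at least 2-fold required the same adjusted p and an absolute log2 ratio of 1 or more. Versions were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

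The 25 gene lists, written from general knowledge, held 421 distinct genes in 432 memberships, all present in the file. They were heat shock and proteostasis, warm-temperature growth with PIF4 and auxin, circadian clock, salicylic acid defence, jasmonate, abscisic acid response, cold and CBF regulon, photorespiration, Calvin-Benson cycle, light harvesting, CO2 sensing and stomata, starch synthesis and starch degradation. The others were carbon starvation, anthocyanin and flavonoid, nitrogen uptake and assimilation, aliphatic glucosinolate, indole glucosinolate and camalexin, oxidative stress, endoplasmic reticulum unfolded protein response, cell division, leaf senescence, flowering time, touch and wounding at harvest, and markers of other organs and cell types. Camera tested each list on log CPM (prior count 2) with a preset correlation of 0.01, adjusted over the 25 lists of a comparison, and again with an estimated correlation. Lists not called by camera are reported in part, and calls by fry only as numbers.

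Genes were named by rule. Named in every comparison were HSP101, HSP70-4, PIF4, YUC8, PR1, VSP2, COR15A, CHS, GPT2, ASN1, CCA1 and BCA1. Also named were the 5 highest and 5 lowest genes with an adjusted p under 0.05, a mean of at least 1 CPM, a symbol and the same sign in at least 75% of pairs, and the 2 smallest adjusted p of each list called by camera. These additions applied to warming at ambient CO2, CO2 at 22 °C, both treatments and the interaction, and the other comparisons repeat genes named there. LHY, TOC1, ELF4, FKF1, DFR, LDOX, BIP3, PYK10 and GC1 are given where they fall outside the rule, and these were chosen after their values were seen.

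Alternatives were limma-voom, DESeq2, RLE factors, robust fitting, other count filters, removal of organelle and ribosomal genes, dates as blocks, each week left out, only the groups compared, and single libraries left out. They also included leaving out 3 libraries that stand apart (replicates 16 and 24 under both treatments and replicate 14 at elevated CO2). For lists, fry was a further test. Leaving out these 3 libraries or control replicates 5 and 11, and blocks with an estimated correlation, were added after results had been seen. Permutation tests used 100000 resamples, so the smallest possible p is 1e-05. Groups were also exchanged at random, the real grouping counting as 1 of 25 splits per comparison. In simulated data made from warming at ambient CO2, 28%, 74%, 90% and 100% of genes changed 1.25-, 1.5-, 2- and 4-fold were found (50 genes each), 3.66% of calls were false, and an unchanged comparison gave 0 calls.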

Results

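Leaf RNA of the Arabidopsis thaliana accession Col-0 was compared between 4 groups, grown at ambient or elevated CO2 (1000 ppm) and kept at 22 °C or moved to 30 °C. There were 22 libraries each of the control (ambient CO2, 22 °C), of 30 °C alone and of elevated CO2 alone, and 21 of both treatments, each group spread over the same batch dates. The 87 libraries held 2.26e7 to 7.37e7 counts, of which 9.95e6 to 3.48e7 fell on nuclear genes. Changes are given below as log2 ratio ± standard error, followed in parentheses by the adjusted p of edgeR's quasi-likelihood test with Benjamini-Hochberg correction and by the number of same-date library pairs with the same sign (for the interaction, sets of 4). Levels are mean CPM (counts scaled to library size) ± standard deviation of the libraries of a group. For lists, parentheses give the higher and lower counts when adjusted over the list alone, the median log2 ratio, and the camera adjusted p with a preset and with an estimated correlation between members ("estimated"). With the latter no list was called in any comparison. Mean and test direction are added where they differ in sign from the median. Members named beside a count of 5 or fewer were chosen after their values were seen.

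Transcripts of the chloroplast genome made up 46.8% to 67.5% of the counts of each library. Elevated CO2 at 22 °C lowered this share and raised the far smaller mitochondrial share. At 22 °C, the chloroplast share fell from 55.7% ± 2.33 to 52.5% ± 3.39 of counts with elevated CO2 (permutation adjusted p = 0.0034, lower in 18 of 22 pairs). The mitochondrial share rose from 0.996% ± 0.173 to 1.19% ± 0.195 (adjusted p = 0.0034, higher in 19 of 22 pairs). At 30 °C the mitochondrial share also rose with elevated CO2, from 0.940% ± 0.214 to 1.13% ± 0.145 (adjusted p = 0.00397, 19 of 21 pairs), and it was higher under both treatments than in the control (adjusted p = 0.0164, 19 of 21 pairs). Warming at ambient CO2 moved neither share past the test (adjusted p = 0.62 and 0.51), while warming at elevated CO2 came with a chloroplast share 2.94 points higher (adjusted p = 0.0363, 15 of 21 pairs). Comparing medians in place of means, the last difference was 2.7 points and no longer past the test (adjusted p = 0.109). With dates as blocks, elevated CO2 at 22 °C changed the chloroplast share by -3.21 points (adjusted p = 0.0015). Each p came from 100000 two-sided resamples in a family of 10 tests.

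**Figure D1:**
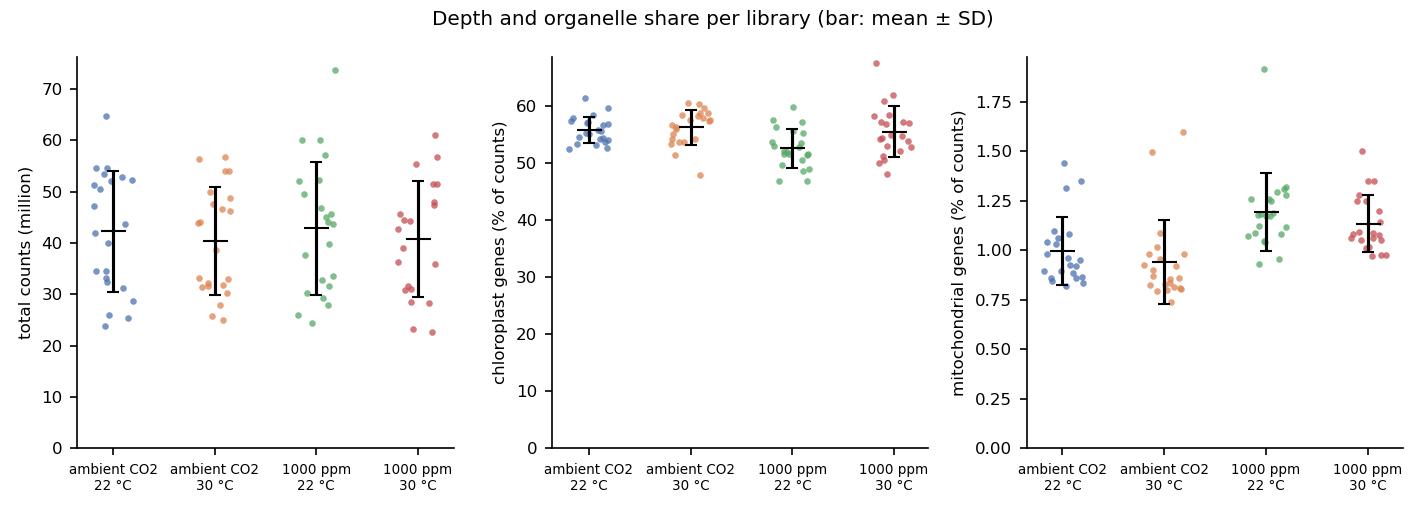
Total counts, chloroplast share and mitochondrial share (both % of counts) of each library, by group, with bars at the mean and standard deviation. The chloroplast share of the group at elevated CO2 and 22 °C, 52.5%, lay below the 55.7% of the control.

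Warming at ambient CO2 raised part of the chaperone transcripts and lowered most defence and cold-response transcripts, in lists called with the preset correlation only. This comparison of 22 libraries at 30 °C with 22 at 22 °C asks what warming at ambient CO2 does. One label gives 30 h of light at 30 °C and 16 h at 22 °C, so light cannot be held apart from warming. Transcripts of HSP70-4 (AT3G12580), a cytosolic chaperone of heat-stressed cells, rose from 2.86 ± 3.58 to 41.2 ± 24.6 CPM. Those of PR1 (AT2G14610), a secreted marker protein of salicylic acid signalling, fell from 68.2 ± 220.3 to 0.622 ± 1.73 CPM. COR15A (AT2G42540), which protects chloroplast membranes in the cold, fell from 287 ± 156 to 35.5 ± 24.3 CPM, and the morning clock gene CCA1 (AT2G46830) rose from 1.97 ± 0.672 to 14.1 ± 3.77 CPM. In all, 4837 genes were higher and 4818 lower of 19589 tested (edgeR adjusted p under 0.05), and 1502 of them changed at least 2-fold. In single weeks, log2 ratios correlated with those of the other weeks across all tested genes, which are not independent replicates, at r = 0.635 to 0.848. Of the genes called in the other weeks, 93.0% to 97.9% kept their sign.

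HSP70-4 rose by 3.83 ± 0.32 (edgeR adjusted p = 1.43e-17, 22 of 22). HSP101 (AT1G74310), the disaggregase needed for acquired thermotolerance, rose by 0.79 ± 0.18 (edgeR adjusted p = 0.000188, 20 of 22). MBF1C (AT3G24500), a transcriptional coactivator tied to thermotolerance, rose by 1.81 ± 0.14 (edgeR adjusted p = 8.12e-19, 22 of 22). Of the heat shock and proteostasis list, 15 of 23 members were higher, 0 lower and 8 not past the test (the same over the list alone, median 0.80, camera adjusted p = 0.000118, and 0.323 estimated). Hop3 (AT4G12400), a co-chaperone linking HSP70 and HSP90, rose by 3.80 ± 0.32 (edgeR adjusted p = 6.56e-18, 22 of 22). Among the warm-growth, PIF4 and auxin genes, 12 of 19 members were higher, 2 lower (IAA29 and CYP79B2) and 5 not past the test (the same over the list alone, median 0.64, camera adjusted p = 0.032, and 0.995 estimated). Within it, HFR1 (AT1G02340), a brake on PIF transcription factors, rose by 2.29 ± 0.33 (edgeR adjusted p = 8.63e-09, 22 of 22). PIF5 (AT3G59060), itself a PIF, rose by 0.42 ± 0.063 (edgeR adjusted p = 2.67e-08, 21 of 22). PIF4 (AT2G43010), the central thermosensory growth regulator, had 0.079 ± 0.11 (edgeR adjusted p = 0.57, 11 of 22), and the auxin synthesis gene YUC8 (AT4G28720) had -0.31 ± 0.24 (0.274, 15 of 22), neither past the test. Among called genes, the largest rise was that of BHLH100 (AT2G41240), an iron-deficiency transcription factor, at 5.82 ± 0.87 (edgeR adjusted p = 2.88e-08, 21 of 22). It was larger, 6.71 in place of 6.04 as log2 ratio of means, without control replicate 5. DR4 (AT1G73330), a Kunitz-type inhibitor repressed by drought, rose by 3.35 ± 0.71 (edgeR adjusted p = 4.77e-05, 21 of 22) and by 4.26 in place of 3.26 as log2 ratio of means without control replicate 18. COL2 (AT3G02380), a CONSTANS-like B-box regulator, rose by 3.27 ± 0.17 (edgeR adjusted p = 6.12e-29, 22 of 22).

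Salicylic acid defence and camalexin genes had falls among the largest at 30 °C. Of the salicylic acid list, 0 of 26 members were higher, 22 lower and 4 not past the test (0 and 24 over the list alone, median -2.29, camera adjusted p = 1.08e-06, and 0.754 estimated). PR1 fell by 6.88 ± 1.14 (edgeR adjusted p = 3.71e-07, 18 of 22), PR5 (AT1G75040), a thaumatin-like defence protein, by 6.05 ± 0.71 (1.16e-11, 21 of 22), and NUDT6 (AT2G04450), a nudix hydrolase of this response, by 4.35 ± 0.51 (1.18e-11, 21 of 22). ALD1 (AT2G13810), which starts pipecolic acid synthesis, fell by 8.01 ± 1.08 (edgeR adjusted p = 1.5e-09, 17 of 22). ABCG40 (AT1G15520), a plasma membrane transporter, fell by 7.98 ± 1.06 (edgeR adjusted p = 8.62e-10, 18 of 22). PAD3 (AT3G26830) and CYP71A13 (AT2G30770), enzymes of camalexin synthesis, fell by 7.35 ± 1.02 (edgeR adjusted p = 2.85e-09, 19 of 22) and 7.26 ± 1.08 (2.01e-08, 19 of 22). BG3 (AT3G57240), a glucanase of pathogen responses, fell by 7.01 ± 0.63 (edgeR adjusted p = 2.21e-16, 20 of 22). Without control replicate 5, the log2 ratio of means went from -8.25 to -6.49 for ALD1, from -7.98 to -6.54 for ABCG40, from -7.42 to -6.11 for CYP71A13, from -7.37 to -6.18 for PAD3 and from -4.33 to -3.54 for NUDT6. Without replicate 11 it went from -6.78 to -5.25 for PR1 and from -6.06 to -4.78 for PR5. With limma-voom, PR1 (-5.25, adjusted p = 0.0544), ABCG40 (-4.05, 0.071) and CYP71A13 (-3.47, 0.082) were no longer past the test. The list median was negative in all 6 weeks, from -3.51 in week 1 to -0.36 in week 5. Indole glucosinolate and camalexin genes as a list were not called (2 higher, MYB34 and SOT16, and 4 lower, PAD3, CYP71A13, CYP83B1 and CYP79B2, of 9, median -0.44, camera adjusted p = 0.674).

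In the cold and CBF list, 1 of 17 members was higher (CBF2), 13 lower and 3 not past the test (the same over the list alone, median -1.55, camera adjusted p = 3.86e-08, and 0.323 estimated). COR15A fell by 3.01 ± 0.33 (edgeR adjusted p = 9.17e-13, 22 of 22), its neighbour COR15B (AT2G42530) by 2.78 ± 0.23 (1.07e-17, 22 of 22), and RD29A (AT5G52310), a classical drought and cold gene, by 3.27 ± 0.29 (1.14e-16, 22 of 22). For light harvesting, 0 of 21 members were higher, 11 lower and 10 not past the test (the same over the list alone, median -0.23, camera adjusted p = 0.029, and 0.995 estimated). Its members LHCB1.3 (AT1G29930) and LHCB1.4 (AT2G34430), near-identical antenna genes of photosystem II, fell by 0.74 ± 0.090 (edgeR adjusted p = 4.14e-11, 22 of 22) and 0.97 ± 0.14 (1.18e-08, 22 of 22). Starch degradation genes were lower as a list: 1 of 14 members was higher (BAM1), 11 lower and 2 not past the test (the same over the list alone, median -0.39, camera adjusted p = 0.00304, and 0.754 estimated). ISA3 (AT4G09020), a debranching enzyme, fell by 0.97 ± 0.093 (edgeR adjusted p = 5.27e-15, 22 of 22). PHS2 (AT3G46970), a cytosolic glucan phosphorylase, fell by 0.98 ± 0.11 (edgeR adjusted p = 7.23e-13, 22 of 22). Aliphatic glucosinolate genes were higher as a list: 12 of 19 members were higher, 0 lower and 7 not past the test (12 and 1 over the list alone, median 0.40, camera adjusted p = 0.0413, and 0.995 estimated). There, CYP79F2 (AT1G16400), which starts the synthesis of long-chain forms, rose by 1.56 ± 0.23 (edgeR adjusted p = 1.94e-08, 21 of 22). Its activator MYB29 (AT5G07690) rose by 0.63 ± 0.15 (edgeR adjusted p = 0.000357, 20 of 22).

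For the circadian clock, 10 of 22 members were higher, 8 lower and 4 not past the test (11 and 8 over the list alone, median 0.073, camera adjusted p = 0.0561). CCA1 rose by 2.83 ± 0.16 (edgeR adjusted p = 1.11e-26, 22 of 22). With the 3 libraries that stand apart left out, the clock list was called (adjusted p = 0.0464). Also not called were nitrogen uptake and assimilation (4 higher, NIA2, NIA1, GLN1.2 and GLU1, and 6 lower of 18, median -0.15, camera adjusted p = 0.826) and abscisic acid response (7 higher and 3 lower, RD29A, ABI2 and RD22, of 17, median 0.58, mean 0.35, tested down, camera adjusted p = 0.862). Nor were oxidative stress genes (2 higher, UPOX and AOX1A, and 3 lower, CAT1, APX1 and AOX1D, of 11, median 0.30, mean -0.12, tested down, camera adjusted p = 0.872). The same held for jasmonate (3 higher, JAZ8, JAZ6 and LOX3, and 2 lower, TAT3 and AOS, of 21, median 0.28, camera adjusted p = 0.872) and for touch and wounding at harvest (1 higher, JAZ8, and 0 lower of 10, median 0.72, mean 0.60, tested down, camera adjusted p = 0.988). The storage protein gene VSP2 (AT5G24770), a jasmonate reporter, had 0.26 ± 0.81 (edgeR adjusted p = 0.813, 12 of 22), the flavonoid entry gene CHS (AT5G13930) had 0.61 ± 0.35 (0.142, 15 of 22), and the carbonic anhydrase gene BCA1 (AT3G01500) had 0.22 ± 0.14 (0.212, 17 of 22), none past the test. Without replicate 18 of the warmed group, the log2 ratio of means of VSP2 turned from 0.26 to -0.63. ASN1 (AT3G47340), an asparagine synthetase of sugar-starved leaves, rose by 0.87 ± 0.35 (edgeR adjusted p = 0.034, 13 of 22), though not with limma-voom (0.61, adjusted p = 0.221). GPT2 (AT1G61800), a plastid glucose 6-phosphate carrier, had -1.41 ± 0.61 (edgeR adjusted p = 0.0456, 9 of 22), and this call rested on control replicate 5: without it, the value was -0.07 (adjusted p = 0.933). With dates as blocks GPT2 was 0.12 (adjusted p = 0.883).

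Elevated CO2 at 22 °C lowered part of the transcripts for photorespiration, the Calvin-Benson cycle and starch breakdown, and raised some of defence, and this comparison of 22 libraries at 1000 ppm with 22 controls answers what CO2 alone does. BCA1, whose enzyme hydrates CO2 in leaves, fell from 582 ± 108 to 394 ± 139.7 CPM. PR1 rose from 68.2 ± 220.3 to 411 ± 601 CPM, a spread wider than its mean. The morning clock genes CCA1 and LHY (AT1G01060) rose from 1.97 ± 0.672 to 6.62 ± 2.63 and from 0.663 ± 0.293 to 4.43 ± 2.08 CPM. In all, 3816 genes were higher and 2510 lower (edgeR adjusted p under 0.05), 712 of them at least 2-fold. Across all tested genes, which are not independent replicates, each week's log2 ratios correlated with those of the others at r = 0.563 to 0.722. Genes called in the other weeks kept 82.1% to 95.8% of signs.

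Parts of photosynthetic carbon metabolism were lower. Of the photorespiration list, 1 of 23 members was higher (BASS6), 10 lower and 12 not past the test (1 and 11 over the list alone, median -0.22, camera adjusted p = 0.000687, and 0.587 estimated). HPR1 (AT1G68010), the peroxisomal hydroxypyruvate reductase, fell by 0.49 ± 0.093 (edgeR adjusted p = 3.37e-05, 20 of 22), while BASS6 (AT4G22840), a plastid glycolate exporter and the only member that rose, had 0.62 ± 0.13 (0.000253, 18 of 22). Among Calvin-Benson genes, 0 of 21 members were higher, 8 lower and 13 not past the test (the same over the list alone, median -0.18, camera adjusted p = 0.00028, and 0.587 estimated). CP12-2 (AT3G62410), which binds phosphoribulokinase in the dark, fell by 0.54 ± 0.11 (edgeR adjusted p = 8.53e-05, 19 of 22), and that kinase, PRK (AT1G32060), by 0.41 ± 0.093 (0.000464, 21 of 22). In the CO2 sensing and stomata list, 1 of 18 members was higher (MPK4), 6 lower and 11 not past the test (the same over the list alone, median -0.12, camera adjusted p = 0.0408, and 0.587 estimated). BCA1 fell by 0.56 ± 0.14 (edgeR adjusted p = 0.00165, 19 of 22) and its plasma membrane relative BCA4 (AT1G70410) by 0.27 ± 0.075 (0.00362, 18 of 22). For starch degradation, 0 of 14 members were higher, 9 lower and 5 not past the test (0 and 10 over the list alone, median -0.42, camera adjusted p = 3.44e-06, and 0.542 estimated). AMY3 (AT1G69830), a plastid amylase, fell by 0.65 ± 0.081 (edgeR adjusted p = 2.1e-09, 22 of 22). PWD (AT5G26570), which phosphorylates starch granules, fell by 0.71 ± 0.093 (edgeR adjusted p = 1.15e-08, 22 of 22). Starch synthesis genes (3 higher, GBSS1, APL3 and GPT2, and 9 lower of 16, median -0.28, mean 0.027, tested down, camera adjusted p = 0.0814) were called only without the 3 libraries (adjusted p = 0.0431).

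Some defence and endoplasmic reticulum genes were higher. In the salicylic acid list, 10 of 26 members were higher, 0 lower and 16 not past the test (13 and 0 over the list alone, median 0.87, camera adjusted p = 3.62e-06, and 0.587 estimated). SAG101 (AT5G14930), a partner of the immune regulator EDS1, rose by 0.66 ± 0.14 (edgeR adjusted p = 0.000117, 22 of 22). DMR6 (AT5G24530), a salicylic acid hydroxylase, rose by 1.34 ± 0.30 (edgeR adjusted p = 0.000433, 19 of 22). PR1 rose by 2.59 ± 0.91 (edgeR adjusted p = 0.022, 20 of 22), to a log2 ratio of means of 4.12 without control replicate 11, and was not past the test without the 3 libraries (2.17, adjusted p = 0.0523). Among unfolded protein response genes, 8 of 13 members were higher, 0 lower and 5 not past the test (10 and 0 over the list alone, median 0.65, camera adjusted p = 0.00913, and 0.587 estimated). SDF2 (AT2G25110), a lumenal quality control protein, rose by 0.68 ± 0.15 (edgeR adjusted p = 0.000302, 19 of 22). The calreticulin gene CRT1A (AT1G56340) rose by 0.60 ± 0.15 (edgeR adjusted p = 0.00119, 17 of 22). In the leaf senescence list, 5 of 10 members were higher (NYE1, SAG13, NAP, WRKY6 and PPH), 1 lower (NYC1) and 4 not past the test (7 and 1 over the list alone, median 0.81, camera adjusted p = 0.044, and 0.587 estimated). Without the 3 libraries it was not called (adjusted p = 0.0764). NYE1 (AT4G22920), a chlorophyll dechelatase, rose by 0.74 ± 0.15 (edgeR adjusted p = 6.22e-05, 21 of 22), and NYC1 (AT4G13250), the chlorophyll b reductase, fell by 0.70 ± 0.14 (9.11e-05, 21 of 22), against the name of the list. Among the largest rises were those of the defensin genes PDF1.3 (AT2G26010), PDF1.2b (AT2G26020) and PDF1.2c (AT5G44430), at 5.13 ± 0.67 (edgeR adjusted p = 7.25e-09, 20 of 22), 4.25 ± 0.76 (1.17e-05, 19 of 22) and 3.87 ± 0.79 (0.000108, 20 of 22). These near-identical copies cannot be told apart with certainty. The log2 ratio of means went from 4.29 to 3.34 for PDF1.2b without replicate 18 of the elevated CO2 group, and from 3.78 to 5.18 for PDF1.2c without control replicate 18.

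Some growth, cold and cell cycle genes were lower. Among warm-growth, PIF4 and auxin genes, 2 of 19 members were higher (PIF5 and ATHB2), 7 lower and 10 not past the test (the same over the list alone, median -0.39, camera adjusted p = 0.0202, and 0.587 estimated). PRE1 (AT5G39860), a helix-loop-helix promoter of elongation, fell by 0.75 ± 0.19 (edgeR adjusted p = 0.00148, 19 of 22), and PIF5 rose by 0.31 ± 0.063 (7.84e-05, 18 of 22). In the cold list, 2 of 17 members were higher (LTI30 and GOLS3), 7 lower and 8 not past the test (2 and 8 over the list alone, median -0.37, camera adjusted p = 0.00384, and 0.587 estimated). COR27 (AT5G42900) and COR28 (AT4G33980), cold-induced repressors of clock genes, fell by 1.69 ± 0.25 (edgeR adjusted p = 1.55e-07, 21 of 22) and 1.18 ± 0.25 (0.000189, 21 of 22), and COR15A by 0.82 ± 0.31 (0.0334, 15 of 22). In the fit of only the groups compared, COR15A was not past the test (-0.81, adjusted p = 0.051). Of the cell division list, 0 of 9 members were higher, 2 lower (MCM2 and MCM5) and 7 not past the test (0 and 0 over the list alone, median -0.39, camera adjusted p = 0.00877, and 0.587 estimated). The replicative helicase subunits MCM2 (AT1G44900) and MCM5 (AT2G07690) fell by 0.52 ± 0.19 (edgeR adjusted p = 0.027, 18 of 22) and 0.45 ± 0.18 (0.0494, 18 of 22). MCM5 kept about its size but was not past the test without control replicate 5 (-0.43, adjusted p = 0.0585) or with organelle and ribosomal genes removed (-0.44, 0.0505).

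CAX3 (AT3G51860), a vacuolar calcium exchanger, rose by 3.59 ± 0.75 (edgeR adjusted p = 0.00013, 21 of 22) (log2 ratio of means from 3.62 to 4.53 without control replicate 11), and AHP4 (AT3G16360), a phosphotransfer protein of cytokinin signalling, by 3.57 ± 0.51 (7.64e-08, 17 of 22). RVE2 (AT5G37260), a clock-regulated MYB gene, fell by 2.50 ± 0.18 (edgeR adjusted p = 3.36e-19, 22 of 22), and JMJD5 (AT3G20810), a clock-linked demethylase gene, by 2.18 ± 0.18 (2.01e-16, 22 of 22). NIG1 (AT5G46830), a bHLH gene, fell by 1.86 ± 0.33 (edgeR adjusted p = 9.5e-06, 21 of 22), CYP71A25 (AT3G48280), a cytochrome P450 gene, by 1.83 ± 0.21 (5.68e-11, 19 of 22), and XTH17 (AT1G65310), a wall-loosening hydrolase gene, by 1.81 ± 0.47 (0.00203, 20 of 22). CCA1 rose by 1.74 ± 0.16 (edgeR adjusted p = 8.35e-15, 22 of 22) and GPT2 by 1.75 ± 0.58 (0.0165, 20 of 22), the latter to a log2 ratio of means of 3.16 without control replicate 5. HSP101 fell by 0.50 ± 0.19 (edgeR adjusted p = 0.0304, 19 of 22), but by 0.36 without that library (adjusted p = 0.1). HSP70-4 had -0.38 ± 0.30 (edgeR adjusted p = 0.345, 13 of 22), PIF4 -0.13 ± 0.11 (0.36, 13 of 22), YUC8 -0.25 ± 0.24 (0.438, 15 of 22) and VSP2 -1.29 ± 0.82 (0.224, 14 of 22), none past the test. For VSP2, DESeq2 gave -0.47, and the log2 ratio of means went from -1.29 to -0.52 without control replicate 18. ASN1 had 0.66 ± 0.35 (edgeR adjusted p = 0.138, 12 of 22) and CHS 0.83 ± 0.35 (0.0568, 15 of 22), and only CHS passed with dates as blocks (0.88, adjusted p = 0.0206). The clock list (8 higher and 8 lower of 22, median -0.031, mean 0.21, tested up, camera adjusted p = 0.575) was not called. Of the markers of other organs and cell types, 0 of 7 members were higher, 3 lower (AG, ATML1 and PYK10) and 4 not past the test (1 and 4 over the list alone, median -0.32, camera adjusted p = 0.187). There, the root endoplasmic reticulum body gene PYK10 (AT3G09260) had -2.98 ± 0.94 (edgeR adjusted p = 0.0108, 10 of 22).

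Both treatments against control lowered most defence and cold and some photorespiration and carbon fixation genes, in lists called with the preset correlation only. This comparison of 21 libraries with 22 controls asks what warming and CO2 do together. COR15A fell from 287 ± 156 to 29.8 ± 20.3 CPM and PR1 from 68.2 ± 220.3 to 8.07 ± 16.8 (medians 1.41 and 1.39). ASN1 rose from 1.21 ± 0.736 to 6.00 ± 3.86 CPM. In all, 4942 genes were higher and 4404 lower (edgeR adjusted p under 0.05), 1170 of them at least 2-fold. In single weeks, r with the other weeks across all tested genes was 0.613 to 0.782, and genes called in the other weeks kept 87.9% to 96.2% of signs.

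Of the salicylic acid list, under both treatments, 0 of 26 members were higher, 24 lower and 2 not past the test (0 and 25 over the list alone, median -1.80, camera adjusted p = 2.05e-05, and 0.76 estimated). UGT76B1 (AT3G11340), a glucosyltransferase of defence signals, fell by 7.19 ± 1.07 (edgeR adjusted p = 3.03e-08, 16 of 21), ALD1 by 6.53 ± 0.96 (2.38e-08, 16 of 21), ABCG40 by 5.89 ± 0.91 (8.44e-08, 16 of 21), BG3 by 5.42 ± 0.57 (2.87e-13, 20 of 21) and NUDT6 by 3.60 ± 0.49 (2.91e-09, 18 of 21). PR1 fell by 3.07 ± 0.95 (edgeR adjusted p = 0.00523, 12 of 21), but was not past the test without control replicate 11 (-1.53, adjusted p = 0.133), with dates as blocks (-0.61, adjusted p = 0.656) or with limma-voom (-1.05, adjusted p = 0.491). Without control replicate 5, the log2 ratio of means went from -7.41 to -5.77 for UGT76B1, from -6.67 to -4.92 for ALD1, from -6.00 to -4.56 for ABCG40 and from -3.63 to -2.84 for NUDT6. With limma-voom ALD1 (-3.63, adjusted p = 0.0671) and ABCG40 (-2.72, 0.16) were not past the test. BIP3 (AT1G09080), the stress-inducible lumenal chaperone, fell by 4.89 ± 0.65 (edgeR adjusted p = 1.19e-09, 21 of 21). In the cold list, 1 of 17 members was higher (CBF2), 12 lower and 4 not past the test (the same over the list alone, median -0.85, camera adjusted p = 1.42e-06, and 0.586 estimated). There, COR15A had -3.27 ± 0.34 (edgeR adjusted p = 2.35e-13, 21 of 21) and RD29A had -2.93 ± 0.29 (4.01e-14, 20 of 21).

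Carbon metabolism genes were mostly lower. For photorespiration, 2 of 23 members were higher (GGT1 and CAT2), 12 lower and 9 not past the test (2 and 13 over the list alone, median -0.27, camera adjusted p = 0.000545, and 0.76 estimated). SHM1 (AT4G37930), the mitochondrial serine hydroxymethyltransferase, fell by 0.74 ± 0.10 (edgeR adjusted p = 2.62e-09, 21 of 21). PLGG1 (AT1G32080), the plastid glycolate and glycerate carrier, fell by 0.78 ± 0.11 (edgeR adjusted p = 1.56e-08, 20 of 21). Among Calvin-Benson genes, 1 of 21 members was higher (RBCS2B), 14 lower and 6 not past the test (the same over the list alone, median -0.45, camera adjusted p = 2.26e-06, and 0.586 estimated). RBCS1A (AT1G67090), one of several similar Rubisco small subunit genes, fell by 1.10 ± 0.11 (edgeR adjusted p = 1.75e-14, 21 of 21). RPI3 (AT3G04790), a plastid ribose 5-phosphate isomerase, fell by 0.86 ± 0.095 (edgeR adjusted p = 1.83e-12, 21 of 21). Among starch synthesis genes, 1 of 16 members was higher (GBSS1), 10 lower and 5 not past the test (2 and 12 over the list alone, median -0.55, camera adjusted p = 0.00183, and 0.586 estimated). GBSS1 (AT1G32900), the clock-regulated amylose synthase, was the member that rose, by 1.81 ± 0.17 (edgeR adjusted p = 3.09e-15, 21 of 21), and PGM1 (AT5G51820), the plastid phosphoglucomutase, fell by 0.88 ± 0.10 (1.1e-11, 21 of 21). In starch degradation, 0 of 14 members were higher, 11 lower and 3 not past the test (the same over the list alone, median -0.45, camera adjusted p = 0.000224, and 0.586 estimated). There, PHS2 had -1.004 ± 0.11 (edgeR adjusted p = 1.11e-12, 21 of 21) and ISA3 had -0.65 ± 0.094 (1.73e-08, 21 of 21). Carbon starvation genes were higher as a list: 11 of 18 members were higher, 3 lower (TPS10, GDH2 and TPS11) and 4 not past the test (the same over the list alone, median 0.31, camera adjusted p = 0.0485, and 0.76 estimated). It was not called without the 3 libraries (adjusted p = 0.0616). BZIP63 (AT5G28770), a regulator in low-energy signalling, rose by 1.73 ± 0.12 (edgeR adjusted p = 1.45e-20, 21 of 21). DIN10 (AT5G20250), a dark-inducible raffinose synthase-like gene, rose by 1.399 ± 0.17 (edgeR adjusted p = 4.14e-11, 21 of 21).

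Among the other genes, HSP70-4 rose by 2.26 ± 0.31 (edgeR adjusted p = 3.07e-09, 20 of 21), ASN1 by 2.31 ± 0.36 (1.25e-07, 20 of 21), CCA1 by 1.81 ± 0.16 (2.33e-16, 21 of 21) and PIF4 by 0.29 ± 0.11 (0.0267, 17 of 21). The PIF4 call ended without the 3 libraries (0.25, adjusted p = 0.0529). YUC8 fell by 0.70 ± 0.24 (edgeR adjusted p = 0.0129, 16 of 21). BHLH100 rose by 4.55 ± 0.85 (edgeR adjusted p = 6.25e-06, 16 of 21), or 3.56 in place of 4.75 as log2 ratio of means without replicate 5 under both treatments. CAX3 rose by 3.86 ± 0.76 (edgeR adjusted p = 1.51e-05, 18 of 21) (log2 ratio of means from 3.89 to 4.80 without control replicate 11), CML41 (AT3G50770), a calmodulin-like protein gene, by 3.68 ± 0.75 (3.22e-05, 17 of 21), AHP4 by 3.54 ± 0.51 (1.27e-08, 21 of 21) and Hop3 by 2.88 ± 0.31 (1.04e-12, 21 of 21). HSP101 had -0.11 ± 0.19 (edgeR adjusted p = 0.646, 10 of 21), VSP2 -1.64 ± 0.84 (0.102, 16 of 21), CHS -0.45 ± 0.35 (0.296, 14 of 21), GPT2 -1.34 ± 0.61 (0.0609, 7 of 21) and BCA1 -0.30 ± 0.15 (0.0864, 16 of 21), none past the test. Without control replicate 5 the log2 ratio of means of GPT2 went from -1.36 to 0.033, while DESeq2 called GPT2 (-1.39, adjusted p = 0.0351). With dates as blocks BCA1 passed (-0.38, adjusted p = 0.0193). VSP2 passed with limma-voom (-2.10, adjusted p = 0.0269) and DESeq2 (-1.97, 0.00746), its ratio going from -1.64 to -2.78 without replicate 18 of this group. The warm-growth, PIF4 and auxin list (11 higher and 3 lower, CYP79B2, TAA1 and YUC8, of 19, median 0.39, camera adjusted p = 0.0523) was called only with dates as blocks (adjusted p = 0.0389) and with RLE size factors (0.0468).

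Warming at elevated CO2 was tested with 21 and 22 libraries, to ask whether leaves kept at 1000 ppm respond to 30 °C. 5137 genes were higher and 5308 lower (edgeR adjusted p under 0.05), 1723 of them at least 2-fold. Between each week and the others, r was 0.767 to 0.846 across all tested genes. Genes called in the other weeks kept 89.4% to 95.2% of signs. In the salicylic acid list, 0 of 26 members were higher, 25 lower and 1 not past the test (the same over the list alone, median -2.73, camera adjusted p = 2.13e-11, and 0.818 estimated). PR1 fell by 5.66 ± 1.07 (edgeR adjusted p = 5.23e-06, 19 of 21) (log2 ratio of means from -5.67 to -6.34 without replicate 15 under both treatments). For the unfolded protein response, 0 of 13 members were higher, 12 lower and 1 not past the test (the same over the list alone, median -0.91, camera adjusted p = 0.00585, and 0.818 estimated). There, BIP3 had -6.16 ± 0.67 (edgeR adjusted p = 6.52e-13, 20 of 21) and SDF2 had -0.52 ± 0.15 (0.00291, 10 of 21). Among indole glucosinolate and camalexin genes, 1 of 9 members was higher (MYB34), 8 lower and 0 not past the test (the same over the list alone, median -1.09, camera adjusted p = 0.0442, and 0.818 estimated). PAD3 fell by 3.82 ± 0.79 (edgeR adjusted p = 2.93e-05, 18 of 21). Among cold genes, 2 of 17 members were higher (CBF3 and CBF2), 10 lower and 5 not past the test (the same over the list alone, median -0.64, camera adjusted p = 0.0287, and 0.818 estimated). COR15A fell by 2.45 ± 0.33 (edgeR adjusted p = 9.28e-10, 19 of 21). In the warm-growth list, 13 of 19 members were higher, 2 lower (CYP79B2 and TAA1) and 4 not past the test (the same over the list alone, median 0.72, camera adjusted p = 0.00252, and 0.818 estimated). There, PIF4 had 0.42 ± 0.11 (edgeR adjusted p = 0.000898, 15 of 21) and YUC8, not past the test, had -0.46 ± 0.24 (0.107, 13 of 21). Among carbon starvation genes, 11 of 18 members were higher, 3 lower (BCAT2, TPS10 and GDH2) and 4 not past the test (the same over the list alone, median 0.51, camera adjusted p = 0.0442, and 0.818 estimated). ASN1 rose by 1.65 ± 0.35 (edgeR adjusted p = 4.59e-05, 18 of 21). Without the 3 libraries, the carbon starvation (adjusted p = 0.0514) and indole glucosinolate (0.0582) lists were not called.

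HSP70-4 rose by 2.64 ± 0.31 (edgeR adjusted p = 2.15e-11, 20 of 21). HSP101 had 0.39 ± 0.19 (edgeR adjusted p = 0.0722, 15 of 21), which passed the test with dates as blocks (0.40, adjusted p = 0.0466). CHS fell by 1.29 ± 0.36 (edgeR adjusted p = 0.00159, 19 of 21) and GPT2 by 3.09 ± 0.63 (2.51e-05, 19 of 21) (log2 ratio of means from -3.13 to -3.81 without replicate 15 under both treatments). LHY fell by 2.89 ± 0.19 (edgeR adjusted p = 1.28e-22, 21 of 21) while CCA1 had 0.065 ± 0.15 (0.743, 12 of 21), and VSP2 had -0.35 ± 0.82 (0.743, 12 of 21) and BCA1 0.27 ± 0.15 (0.111, 12 of 21), these 3 not past the test. DESeq2 called VSP2 (-1.49, adjusted p = 0.0424), and its log2 ratio of means went from -0.35 to -1.49 without replicate 18 under both treatments. The leaf senescence list (0 higher and 8 lower of 10, median -0.62, camera adjusted p = 0.053) was called only with dates as blocks (adjusted p = 0.0321).

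Elevated CO2 at 30 °C lowered some photorespiration, heat shock and anthocyanin transcripts. This comparison of 21 with 22 libraries asks whether warm leaves respond to CO2. HSP70-4 fell from 41.2 ± 24.6 to 13.9 ± 6.53 CPM, and CHS from 16.0 ± 17.7 to 7.68 ± 7.36 CPM. In all, 1730 genes were higher and 937 lower (edgeR adjusted p under 0.05), 357 of them at least 2-fold. Of the called genes 64.9% were higher, against 50.1% with limma-voom. Week 6 stood apart, with r = 0.0822 across all tested genes and 59.0% of signs kept by genes called without that week. The other weeks had r = 0.394 to 0.686 and 81.3% to 96.2%.

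Of the photorespiration list, at 30 °C, 0 of 23 members were higher, 13 lower and 10 not past the test (0 and 18 over the list alone, median -0.32, camera adjusted p = 1.36e-13, and 0.0897 estimated). Its member CAT2 (AT4G35090), the peroxisomal catalase, fell by 0.76 ± 0.16 (edgeR adjusted p = 0.00075, 19 of 21). Among Calvin-Benson genes, 0 of 21 members were higher, 9 lower and 12 not past the test (0 and 10 over the list alone, median -0.32, camera adjusted p = 8.98e-09, and 0.248 estimated). Among starch synthesis genes, 0 of 16 members were higher, 5 lower (GBSS1, SBE2.2, SS2, APS1 and SS1) and 11 not past the test (the same over the list alone, median -0.21, camera adjusted p = 0.000257, and 0.248 estimated). There, GBSS1 had -0.87 ± 0.16 (edgeR adjusted p = 0.000122, 19 of 21). Carbon starvation genes were higher as a list: 9 of 18 members were higher, 0 lower and 9 not past the test (the same over the list alone, median 0.22, camera adjusted p = 0.00209, and 0.303 estimated). ASN1 rose by 1.44 ± 0.35 (edgeR adjusted p = 0.00267, 17 of 21). In the heat shock list, 0 of 23 members were higher, 11 lower and 12 not past the test (0 and 12 over the list alone, median -0.41, camera adjusted p = 1.11e-06, and 0.0897 estimated). HSP70-4 fell by 1.57 ± 0.30 (edgeR adjusted p = 0.000144, 21 of 21) and HSP101 by 0.90 ± 0.19 (0.000447, 19 of 21). Among anthocyanin and flavonoid genes, 1 of 16 members was higher (MYBL2), 7 lower and 8 not past the test (1 and 11 over the list alone, median -1.13, camera adjusted p = 7.38e-05, and 0.303 estimated). The late pathway genes DFR (AT5G42800) and LDOX (AT4G22880) fell by 3.03 ± 0.86 (edgeR adjusted p = 0.0104, 13 of 21) and 2.07 ± 0.70 (0.0339, 15 of 21), and CHS by 1.06 ± 0.36 (0.0344, 17 of 21). The call of CHS ended on leaving out any of weeks 1 to 5 (-0.77 to -1.16, adjusted p = 0.0614 to 0.152), with fewer libraries in the fit.

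Of the clock list, 2 of 22 members were higher (LUX and FKF1), 8 lower and 12 not past the test (3 and 8 over the list alone, median -0.15, camera adjusted p = 0.0248, and 0.354 estimated). In the cold list, 4 of 17 members were higher (COR27, KIN2, COR413IM1 and COR413PM1), 0 lower and 13 not past the test (6 and 1 over the list alone, median 0.22, camera adjusted p = 0.0248, and 0.637 estimated). With dates as blocks neither was called (adjusted p = 0.0546 and 0.055), nor was the cold list without the 3 libraries (0.0928). In the unfolded protein response list, 0 of 13 members were higher, 0 lower and 13 not past the test by edgeR, against 0 higher and 5 lower at an unadjusted p under 0.05, 0 and 2 by limma-voom and 0 and 1 by DESeq2 (the same over the list alone, median -0.24, camera adjusted p = 0.014, and 0.637 estimated). Among flowering time genes, 3 of 9 members were higher (SPL3, MAF2 and SVP), 0 lower and 6 not past the test (the same over the list alone, median 0.14, camera adjusted p = 0.0401, and 0.303 estimated). This call ended without the 3 libraries (adjusted p = 0.0665). Called on few members were aliphatic glucosinolates (0 higher and 2 lower, UGT74C1 and CYP79F2, of 19, median -0.33, camera adjusted p = 0.00456, and 0.637 estimated) and markers of other organs and cell types (0 higher and 1 lower, GC1, of 7, median -0.62, camera adjusted p = 0.0248, and 0.206 estimated). The guard cell gene GC1 (AT1G22690) fell by 1.002 ± 0.17 (edgeR adjusted p = 1.36e-05, 21 of 21), and PYK10, not past the test, had -2.28 ± 0.87 (0.0665, 14 of 21). CCA1 fell by 1.02 ± 0.15 (edgeR adjusted p = 1.74e-06, 20 of 21) and LHY by 1.05 ± 0.19 (5.46e-05, 20 of 21). PAD3 rose by 4.42 ± 0.98 (edgeR adjusted p = 0.00113, 18 of 21). Cell division was called without any member past the edgeR test (0 higher and 0 lower of 9, median -0.26, camera adjusted p = 0.0248, and 0.637 estimated), with 2 lower at an unadjusted p under 0.05 and 0 by limma-voom and DESeq2.

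PR1 rose by 3.81 ± 1.03 (edgeR adjusted p = 0.00708, 17 of 21) (log2 ratio of means from 3.70 to 4.83 without replicate 22 of the warmed group), but this was not past the test with limma-voom (4.21, adjusted p = 0.244). BCA1 fell by 0.51 ± 0.15 (edgeR adjusted p = 0.0116, 17 of 21). VSP2 had -1.89 ± 0.85 (edgeR adjusted p = 0.125, 18 of 21), which passed with dates as blocks (-2.04, adjusted p = 0.0231), limma-voom (-2.56, 0.0272) and DESeq2 (-2.10, 0.015), and its log2 ratio of means went from -1.89 to -3.04 without replicate 18 under both treatments. PIF4 had 0.21 ± 0.11 (edgeR adjusted p = 0.207, 14 of 21), YUC8 -0.39 ± 0.24 (0.291, 14 of 21), COR15A -0.26 ± 0.31 (0.619, 11 of 21) and GPT2 0.070 ± 0.62 (0.954, 10 of 21), none past the test. The log2 ratio of means of GPT2 went from 0.0072 to 0.90 without replicate 18 of the warmed group. The jasmonate list (0 higher and 4 lower, JMT, CORI3, LOX4 and LOX3, of 21, median -0.41, camera adjusted p = 0.0918) was called only with dates as blocks (adjusted p = 0.0333) and without the 3 libraries (0.0415). Light harvesting (1 higher, LHCB1.4, and 3 lower, LHCB4.3, LHCA6 and PSBS, of 21, median 0.15, camera adjusted p = 0.341) was called only without the 3 libraries (adjusted p = 0.00419).

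**Figure D2:**
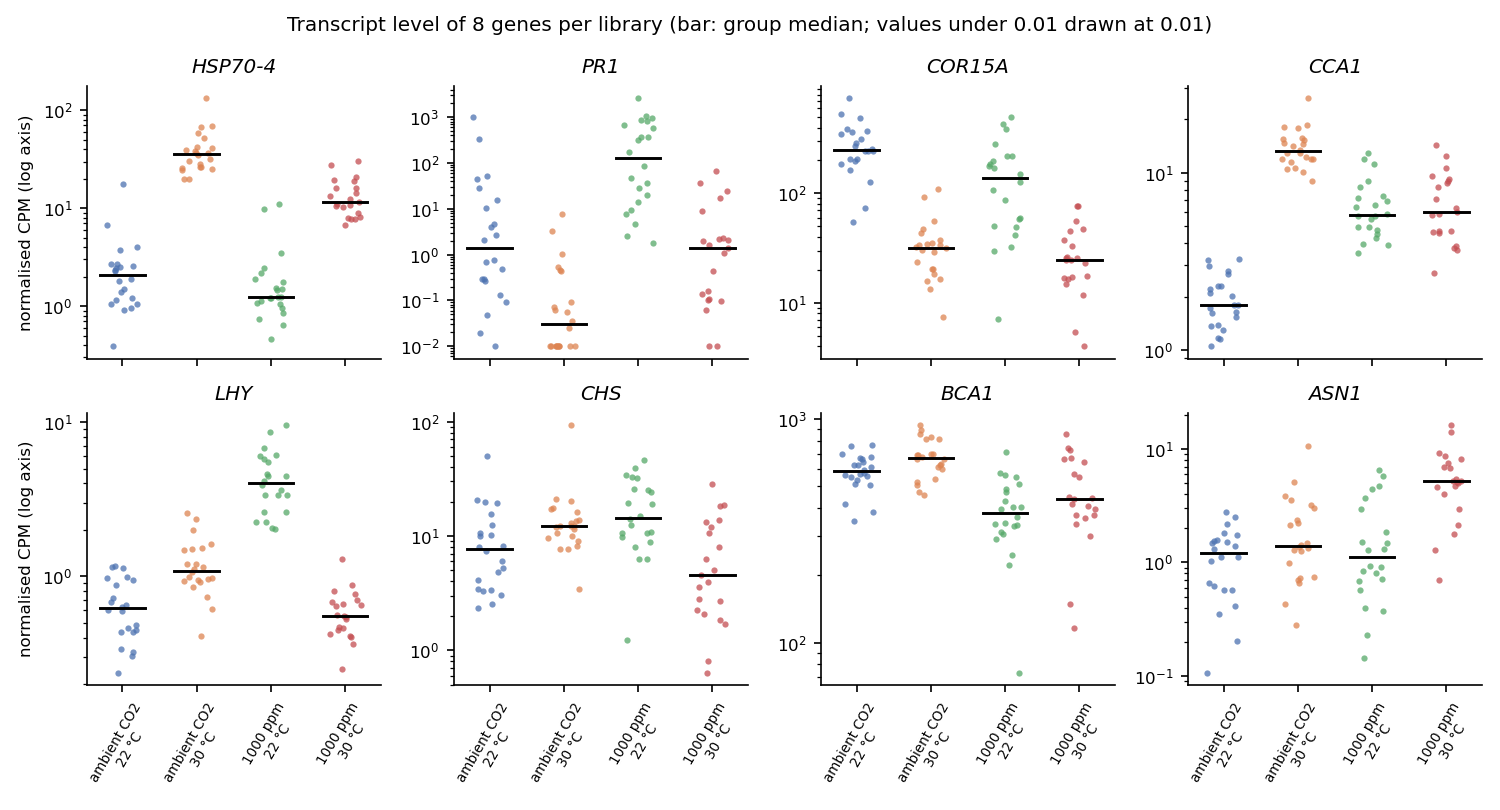
CPM of 8 genes in each library (log axis, values under 0.01 drawn at 0.01), by group, with bars at the median. HSP70-4 stood at 41.2 CPM on average in the warmed group against 13.9 CPM under both treatments, and PR1 spread over several orders of magnitude within groups.

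The interaction tests whether warming acted differently at elevated than at ambient CO2, and clock genes were among those with the smallest adjusted p. Over all 87 libraries, 733 genes had a positive and 825 a negative interaction (edgeR adjusted p under 0.05), 409 of them at least 2-fold. Across all tested genes, weeks had r = 0.285 to 0.510 with the others. Called genes kept 80.1% to 97.8% of signs. CCA1 stood at 1.97 ± 0.672, 14.1 ± 3.77, 6.62 ± 2.63 and 6.94 ± 3.09 CPM in control, 30 °C, elevated CO2 and both. LHY, its partner, stood at 0.663 ± 0.293, 1.23 ± 0.533, 4.43 ± 2.08 and 0.595 ± 0.225 CPM. Their interactions were -2.76 ± 0.22 (edgeR adjusted p = 2.89e-17, 21 of 21) and -3.78 ± 0.27 (5.37e-20, 21 of 21). For lists, higher and lower stand here for positive and negative interactions. RVE8 (AT3G09600), a morning activator, had -2.62 ± 0.20 (edgeR adjusted p = 3.09e-18, 21 of 21), and the evening genes TOC1 (AT5G61380), ELF4 (AT2G40080) and FKF1 (AT1G68050) had 1.30 ± 0.17 (8.37e-09, 21 of 21), 1.27 ± 0.32 (0.00623, 20 of 21) and 1.43 ± 0.21 (6.59e-07, 20 of 21). Of the clock list, 8 of 22 members were higher, 8 lower and 6 not past the test (9 and 9 over the list alone, median -0.031, camera adjusted p = 0.0387, and 0.396 estimated). With dates as blocks it was not called (adjusted p = 0.116).

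Clock-linked and metabolic genes outside that list also had interactions. JMJD5 had an interaction of 2.30 ± 0.25 (edgeR adjusted p = 3.73e-11, 21 of 21). In the cold list, 6 of 17 members were higher, 1 lower (LTI30) and 10 not past the test (7 and 1 over the list alone, median 0.59, camera adjusted p = 2.67e-06, and 0.358 estimated). There, COR27 had 2.81 ± 0.35 (edgeR adjusted p = 3.05e-09, 21 of 21) and KIN2 (AT5G15970), a cold and drought gene, had 1.42 ± 0.27 (0.000115, 20 of 21). Among nitrogen genes, 0 of 18 members were higher, 4 lower (NIA2, NIA1, NRT1.5 and GLN1.2) and 14 not past the test (the same over the list alone, median -0.076, camera adjusted p = 0.0387, and 0.358 estimated). Both nitrate reductase genes, NIA1 (AT1G77760) and NIA2 (AT1G37130), had negative interactions of -1.51 ± 0.26 (edgeR adjusted p = 1.32e-05, 19 of 21) and -1.60 ± 0.21 (3.06e-08, 21 of 21). Blocking on dates ended this list call (adjusted p = 0.0598). For starch degradation, 8 of 14 members were higher, 0 lower and 6 not past the test (8 and 1 over the list alone, median 0.46, camera adjusted p = 3.4e-06, and 0.358 estimated). There, DPE1 (AT5G64860), the plastid disproportionating enzyme, had 0.60 ± 0.10 (edgeR adjusted p = 1.47e-05, 21 of 21) and PWD had 0.69 ± 0.13 (0.00013, 17 of 21). Among carbon starvation genes, 4 of 18 members were higher (DRM1, DIN4, MIOX2 and BT2), 0 lower and 14 not past the test (the same over the list alone, median 0.19, camera adjusted p = 0.00475, and 0.382 estimated). There, DRM1 (AT1G28330), a dormancy-associated gene, had 1.60 ± 0.35 (edgeR adjusted p = 0.000901, 20 of 21) and DIN4 (AT3G13450), a branched-chain keto acid dehydrogenase gene, had 0.42 ± 0.11 (0.00703, 18 of 21). Among light harvesting genes, 2 of 21 members were higher (LHCB1.4 and LHCA2), 1 lower (LHCB4.3) and 18 not past the test (4 and 1 over the list alone, median 0.20, camera adjusted p = 0.0302, and 0.692 estimated). There, LHCB4.3 (AT2G40100) had -1.42 ± 0.22 (edgeR adjusted p = 1.48e-06, 20 of 21) and LHCB1.4 had 0.75 ± 0.20 (0.0086, 18 of 21). CO2 sensing and stomata genes were called (0 higher and 0 lower of 18, median 0.21, camera adjusted p = 0.0158, and 0.47 estimated) with 0 members past the edgeR test and 3 higher at an unadjusted p under 0.05. The stomatal wax gene HIC (AT2G46720) had 0.29 ± 0.13 (edgeR adjusted p = 0.167, 14 of 21) and BCA4 0.24 ± 0.11 (0.171, 17 of 21), neither past the test.

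Several stress and defence lists were called with negative interactions, mostly on few members. For the unfolded protein response, 0 of 13 members were higher, 7 lower and 6 not past the test (0 and 11 over the list alone, median -0.89, camera adjusted p = 2.67e-06, and 0.358 estimated). There, the co-chaperone gene ERDJ3A (AT3G08970) had -2.04 ± 0.46 (edgeR adjusted p = 0.00133, 16 of 21) and SDF2 had -0.92 ± 0.21 (0.00228, 20 of 21). Among heat shock genes, 1 of 23 members was higher (HSFA3), 4 lower (MBF1C, HSP17.6B, HSFB1 and CLPB3) and 18 not past the test (1 and 10 over the list alone, median -0.57, camera adjusted p = 0.000162, and 0.358 estimated). There, MBF1C had -0.76 ± 0.20 (edgeR adjusted p = 0.00886, 16 of 21). HSP17.6B (AT2G29500), one of several similar small heat shock protein genes, had -2.09 ± 0.56 (edgeR adjusted p = 0.0103, 17 of 21), which was not past the test with limma-voom (-1.21, adjusted p = 0.224). In the flavonoid list, 0 of 16 members were higher, 6 lower and 10 not past the test (0 and 9 over the list alone, median -1.22, camera adjusted p = 3.1e-05, and 0.358 estimated). There, CHS had -1.89 ± 0.50 (edgeR adjusted p = 0.00852, 21 of 21) and UGT78D2 (AT5G17050), a flavonol glucosyltransferase gene, had -0.73 ± 0.18 (0.00581, 19 of 21). F3H (AT3G51240), an early flavonoid enzyme gene, had -2.06 ± 0.46 (edgeR adjusted p = 0.00153, 17 of 21) (log2 ratio of means from -2.05 to -1.31 without replicate 18 of the warmed group). Among indole glucosinolate and camalexin genes, 0 of 9 members were higher, 2 lower (SOT16 and CYP83B1) and 7 not past the test (1 and 4 over the list alone, median -0.63, mean 0.15, tested down, camera adjusted p = 0.0148, and 0.382 estimated). There, SOT16 (AT1G74100), a sulfotransferase gene, had -0.56 ± 0.15 (edgeR adjusted p = 0.00739, 18 of 21) and CYP83B1 (AT4G31500), a branch-point monooxygenase gene, had -0.65 ± 0.22 (0.0469, 17 of 21). The call of CYP83B1 ended with dates as blocks (-0.62, adjusted p = 0.0546), without the low-count filter (-0.64, 0.0668), without the 3 libraries (-0.57, 0.088) and without any of weeks 2 to 6 (week 5: -0.41, 0.403). In the salicylic acid list, 0 of 26 members were higher, 1 lower (SARD4) and 25 not past the test (the same over the list alone, median -0.31, camera adjusted p = 0.000734, and 0.592 estimated). There, SARD4 (AT5G52810), which completes pipecolic acid synthesis, had -1.21 ± 0.35 (edgeR adjusted p = 0.0193, 19 of 21) and PAD3, not past the test, had 3.53 ± 1.21 (0.0551, 7 of 21). PAD3 was called with DESeq2 (3.502, adjusted p = 0.0157), but had 0.75 with dates as blocks (0.749) and 0.19 with limma-voom (0.966). Its log2 ratio of means went from 3.501 to 2.32 without control replicate 5. For photorespiration, 0 of 23 members were higher, 2 lower (CAT2 and GLDP2) and 21 not past the test (the same over the list alone, median -0.13, camera adjusted p = 0.0387, and 0.67 estimated). There, CAT2 had -0.75 ± 0.23 (edgeR adjusted p = 0.0262, 18 of 21) and the glycine decarboxylase gene GLDP2 (AT2G26080) had -0.51 ± 0.16 (0.0315, 16 of 21). This list was not called with dates as blocks (adjusted p = 0.0608) or without the 3 libraries (0.0735).

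CSLG2 (AT4G24000), a cellulose synthase-like gene, had -5.09 ± 1.19 (edgeR adjusted p = 0.00247, 19 of 21), but the log2 ratio of means went from -5.25 to -2.03 without replicate 18 of the warmed group. DESeq2 and limma-voom did not call it (-1.98 and -2.68, adjusted p = 0.295 and 0.222). ChlAKR (AT2G37770), a chloroplast aldo-keto reductase gene, had -4.35 ± 0.91 (edgeR adjusted p = 0.000562, 18 of 21), with a log2 ratio of means that went from -4.35 to -2.98 without the same library. PYD4 (AT3G08860), an aminotransferase gene of pyrimidine breakdown, had -3.41 ± 0.95 (edgeR adjusted p = 0.0133, 18 of 21) and DR4 -3.25 ± 0.97 (0.0225, 17 of 21), the latter not past the test with limma-voom (-3.22, adjusted p = 0.0883). The log2 ratio of means of DR4 went from -3.16 to -4.15 without control replicate 18. Positive ends were EXPA16 (AT3G55500), an expansin gene, at 2.47 ± 0.42 (edgeR adjusted p = 1.6e-05, 20 of 21), GER3 (AT5G20630), a germin-like gene, at 2.29 ± 0.62 (0.0104, 18 of 21), and THI2.2 (AT5G36910), a thionin gene, at 2.25 ± 0.68 (0.0241, 18 of 21). GC1 had -1.37 ± 0.23 (edgeR adjusted p = 1.36e-05, 20 of 21). HSP70-4 had -1.19 ± 0.42 (edgeR adjusted p = 0.0641, 15 of 21), which passed without control replicate 5 (-1.60, adjusted p = 0.00257), as did GPT2 at -1.68 ± 0.85 (0.232, 19 of 21) (-3.01, adjusted p = 0.00538). GPT2 also passed with dates as blocks (-3.00, adjusted p = 0.007). HSP101 had -0.40 ± 0.26 (edgeR adjusted p = 0.381, 10 of 21), PIF4 0.34 ± 0.16 (0.178, 16 of 21), YUC8 -0.14 ± 0.34 (0.853, 11 of 21) and PR1 1.22 ± 1.29 (0.632, 8 of 21), none past the test. PR1 turned to -0.88 with dates as blocks and -0.87 with limma-voom, and its log2 ratio of means from 1.10 to -0.42 without control replicate 11. Nor were VSP2 at -0.60 ± 1.15 (edgeR adjusted p = 0.812, 13 of 21), COR15A 0.56 ± 0.43 (0.486, 12 of 21), ASN1 0.78 ± 0.49 (0.367, 15 of 21) and BCA1 0.054 ± 0.20 (0.912, 10 of 21). The log2 ratio of means of VSP2 went from -0.60 to -1.75 without replicate 18 under both treatments. The warm-growth list (1 higher, PRE1, and 1 lower, PIF5, of 19, median 0.25, camera adjusted p = 0.0648) was called only with dates as blocks (adjusted p = 0.0424), and aliphatic glucosinolates (0 higher and 2 lower, MAM3 and CYP79F2, of 19, median -0.24, camera adjusted p = 0.108) only without the 3 libraries (adjusted p = 0.0402).

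**Figure D3:**
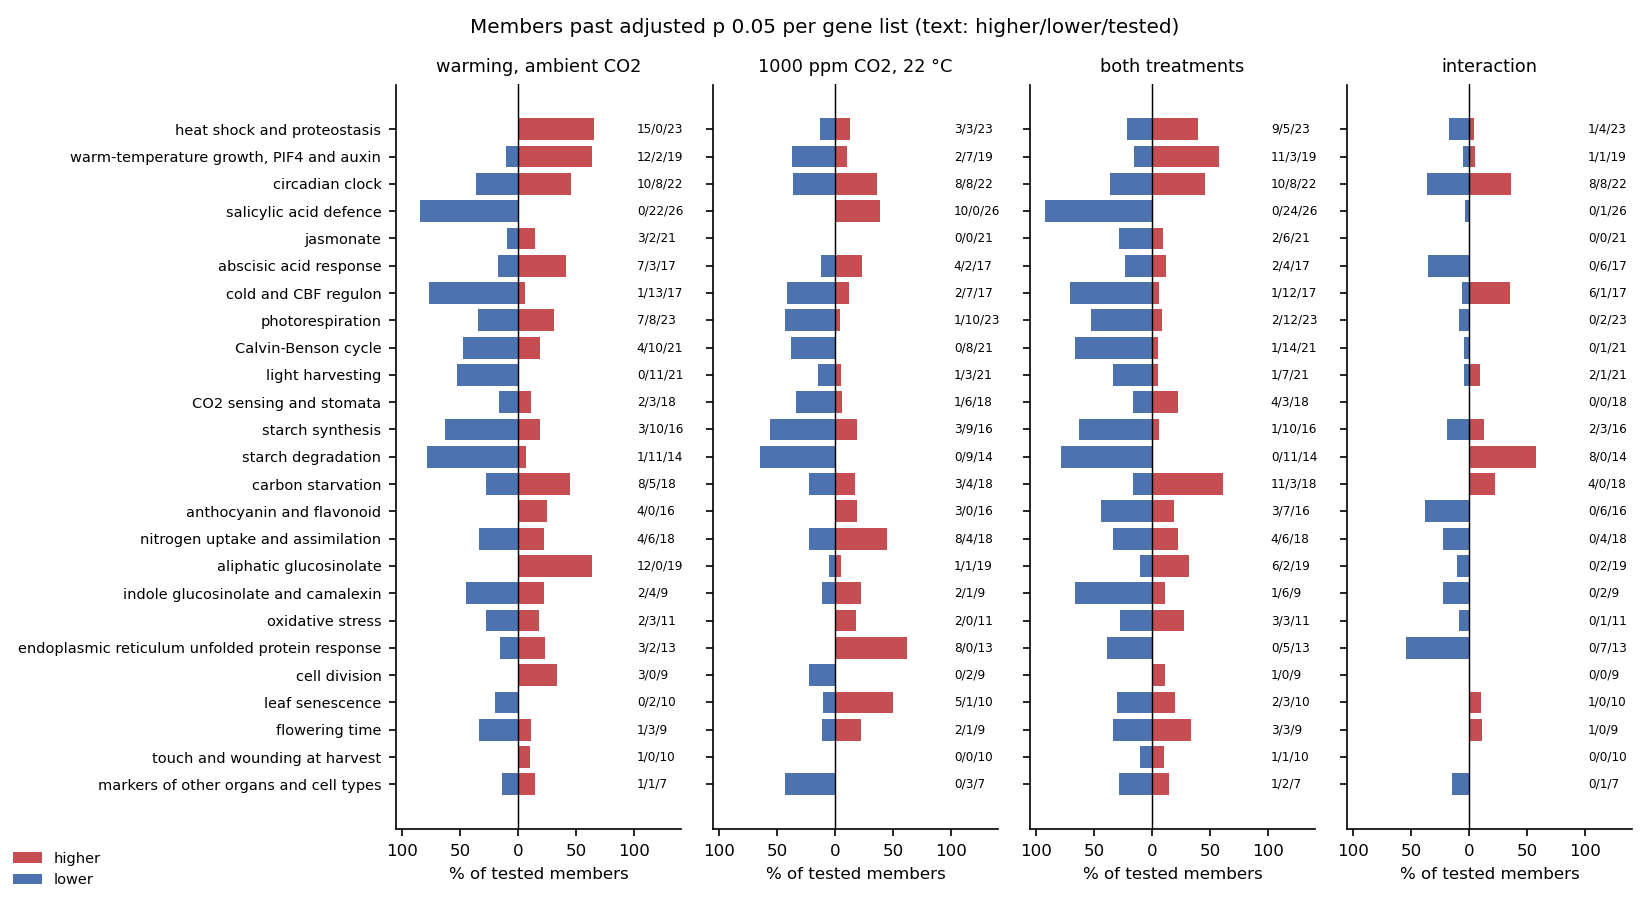
Share of tested members of each list that were higher (red) or lower (blue) in 4 comparisons, in %, with counts written as higher/lower/tested. Salicylic acid genes were lower at 30 °C (22 of 26 members) and higher at elevated CO2 (10 of 26).

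**Figure D4:**
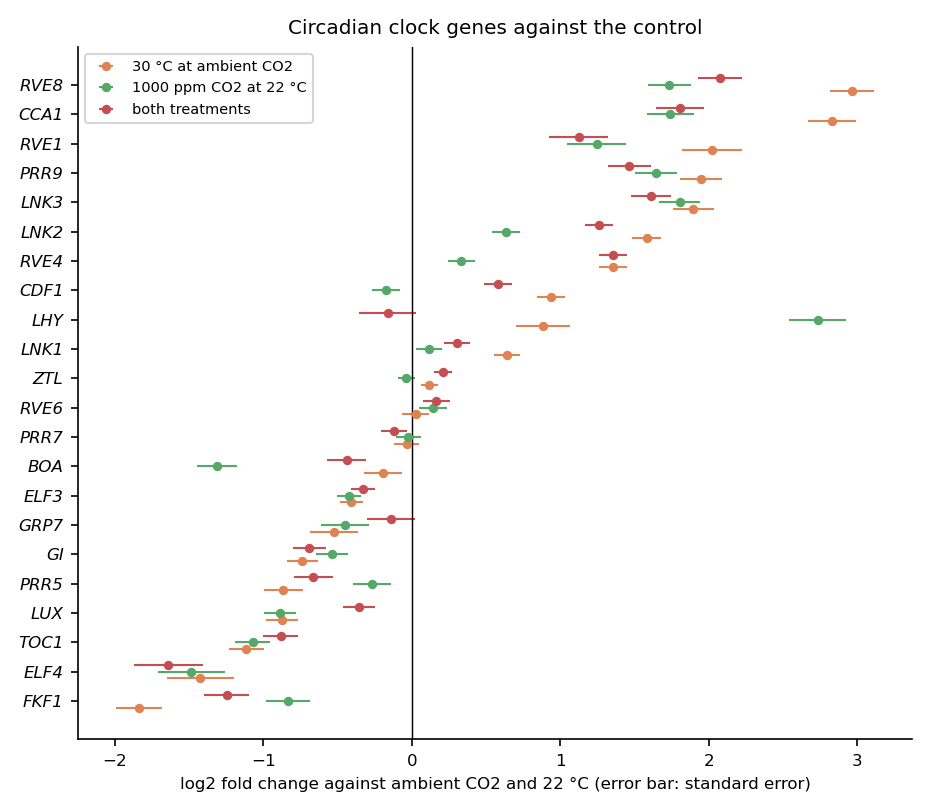
Log2 ratio against control, with standard error bars, of 22 clock genes at 30 °C, at elevated CO2 and under both. CCA1 was higher in all 3 comparisons, at 2.83, 1.74 and 1.81.

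Effects of each treatment were then compared between backgrounds. Warming effects were similar at both CO2 levels: log2 ratios correlated at r = 0.794 across genes, which are not independent replicates, and 98.1% of the 7042 genes called in both had the same sign. Of these, 3409 were higher and 3499 lower in both, where independent lists would share 1268 and 1306. Leaving out 1 week gave r = 0.744 to 0.814. CO2 effects at 22 °C and 30 °C correlated at r = 0.426 (0.309 to 0.467 leaving out 1 week), and 86.3% of 1245 genes had the same sign, 756 higher and 318 lower in both against 337 and 120.1 for independent lists. Passing the test at one temperature and not at the other is no evidence of a difference, which only the interaction tests.

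Effects of warming and of CO2, both taken against the same controls, ran opposite across genes. Their log2 ratios correlated at r = -0.186, and 40.7% of the 3399 genes called in both had the same sign. Of these, 799 were higher in both and 585 lower in both, against 942.3 and 617.3 for independent lists. Shared controls alone push such a correlation upward, to 0.45 on average in 100 simulated sets without effects (-0.088 to 0.837). With controls split between the comparisons r was -0.342 and -0.0941. The splits shared 393 higher and 334 lower against 624.6 and 398.3, and 367 and 268 against 338.6 and 240.5, so fewer and more than independent lists. The covariance of log CPM differences was -0.0449, against 0.0118 in simulation. Clock genes ran against this pattern, with r = 0.837 over 22 genes.

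Within groups, salicylic acid genes varied with other lists (mean log2 CPM scores). At 22 °C they ran with the unfolded protein response, at r = 0.904 in the control (Spearman 0.835, adjusted permutation p = 0.00016 and 0.00024, 0.820 without the 2 farthest libraries, 0.877 within weeks, n = 22). At elevated CO2, r was 0.925 (Spearman 0.905, the same adjusted p-values, 0.914 and 0.936, n = 22). At 30 °C r was 0.235 (Spearman 0.395, adjusted p = 0.363 and 0.13, 0.396 and 0.223, n = 22). Under both it was 0.0123 (Spearman -0.0403, adjusted p = 0.958 and 0.889, -0.0779 and 0.450, n = 21). Neither passed. Salicylic acid scores varied less there (standard deviation 0.337 and 0.720 against 1.46 and 1.415), so r cannot be compared. Leaf senescence genes ran with salicylic acid genes in all 4 groups, at r = 0.843, 0.805, 0.613 and 0.768 (control, elevated CO2, 30 °C, both). Their Spearman values were 0.740, 0.754, 0.605 and 0.744 (largest adjusted p = 0.0135 and 0.0188), with r of at least 0.543 without the 2 farthest libraries and 0.607 within weeks. Light harvesting genes ran opposite at elevated CO2 and 22 °C, at r = -0.686 (Spearman -0.727, adjusted p = 0.00163 and 0.00203, -0.654 and -0.753), while in the control r = -0.515 shrank to -0.136 without 2 libraries. The family held 96 correlations.

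**Figure D5:**
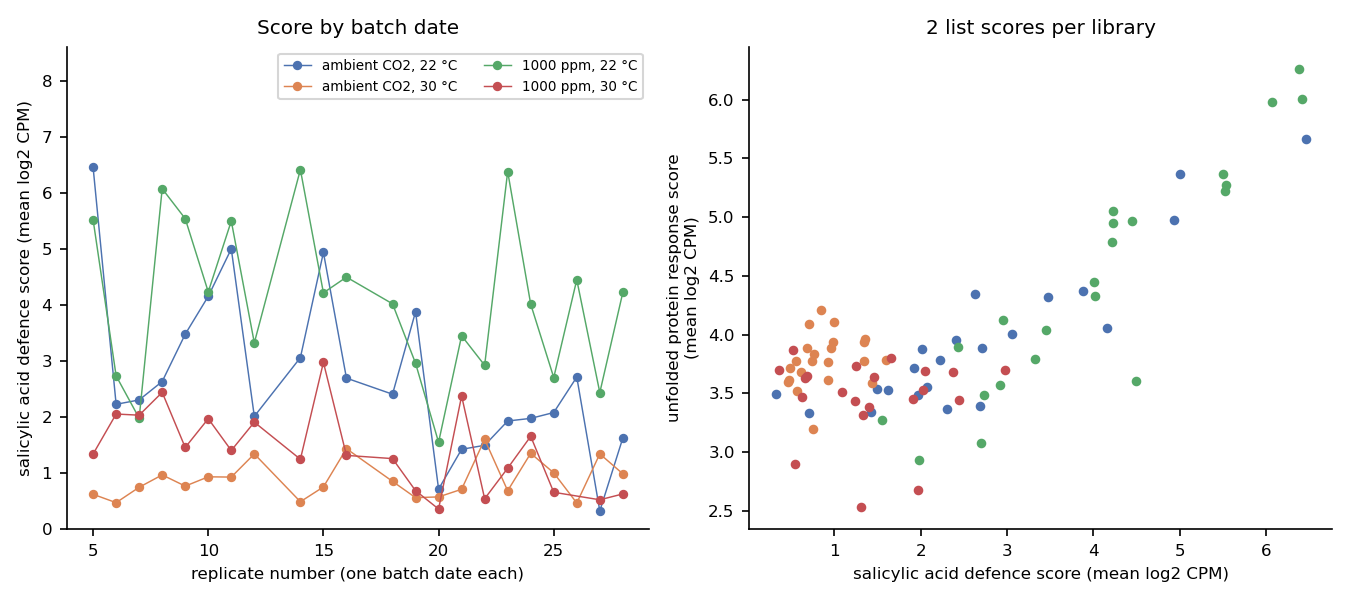
Left, salicylic acid score (mean log2 CPM of the list) of each library by replicate number, coloured by group. Right, this score against the unfolded protein response score, which varied together at 22 °C (r = 0.904 in the control).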

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

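Of the tests in this part, the one on scaling was written before its result was seen and the other 3 were chosen after. Genes named by rule whose response to warming differed between CO2 levels (edgeR adjusted p under 0.05 for the interaction) numbered 33, and TOC1, ELF4, FKF1 and GC1, chosen after their values were seen, passed as well. Among clock and clock-linked genes the log2 interactions were -2.76 for CCA1, -3.78 for LHY, -2.62 for RVE8, 2.81 for COR27 and 2.30 for JMJD5. In nitrate reduction they were -1.51 for NIA1 and -1.60 for NIA2. Heat shock and unfolded protein response genes had -0.76 (MBF1C), -2.09 (HSP17.6B), -2.04 (ERDJ3A) and -0.92 (SDF2), and flavonoid genes -1.89 (CHS), -2.06 (F3H) and -0.73 (UGT78D2). Defence and indole glucosinolate genes had -1.21 (SARD4), -0.56 (SOT16) and -0.65 (CYP83B1). Photosynthesis and photorespiration genes had -0.75 (CAT2), -0.51 (GLDP2), -1.42 (LHCB4.3) and 0.75 (LHCB1.4). Starch, starvation and cold genes had 0.60 (DPE1), 0.69 (PWD), 1.60 (DRM1), 0.42 (DIN4) and 1.42 (KIN2). At the ends of the ranking stood EXPA16 at 2.47, GER3 at 2.29, THI2.2 at 2.25, CSLG2 at -5.09, ChlAKR at -4.35, PYD4 at -3.41 and DR4 at -3.25.

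Most clock genes of the control differed from each treated group, though LHY did not differ under both treatments. Collection of the control alone at another hour was not excluded: 10 of 22 clock genes passed the test for warming at elevated CO2, but so did 53.3% of all genes. It was not the whole cause of clock differences, since 10 of 22 clock genes also passed for CO2 at 30 °C, without the control, against 13.6% of all genes. Collection of each group at its own hour would make the clock profiles of warming and of CO2 alike, and with split controls they correlated at 0.83 (lower of 2 values) across genes, so this account is not excluded and the clock results may reflect the hour of harvest. Scaling or the organelle share is excluded, since 16 clock genes were past the interaction test after organelle and ribosomal genes were removed. On warming at elevated CO2, LHY differed from the median change of CCA1, RVE8, PRR9 and LNK3 by -2.84. Without a time course this cannot test the hour.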

How the results depend on the processing

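In this part, the settings without single libraries and the block with an estimated correlation were chosen after results were seen. Counts of genes changed at least 2-fold were smaller than all called genes, at 1502 for warming at ambient CO2, 712 for CO2 at 22 °C, 1170 for both, 1723 for warming at elevated CO2, 357 for CO2 at 30 °C and 409 for the interaction. The effect of CO2 at 30 °C lost more than 1 in 3 calls on leaving out week 1, 2 or 3 (1399, 1298 and 1479 genes against 2667), and the interaction fell from 1558 to 856 without week 2 and to 720 without week 5. The cause was not tested.

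With an estimated correlation, camera called 0 lists in each of the 6 comparisons. With blocks and an estimated correlation the number was again 0 in each. At an unadjusted p under 0.05 the estimated correlation left 2, 1, 1, 0, 5 and 2 lists, in the order of the counts above, and with blocks 2, 1, 1, 0, 3 and 2. Fry called 11 lists for warming at ambient CO2, 16 for CO2 at 22 °C, 12 for both, 14 for warming at elevated CO2, 9 for CO2 at 30 °C and 9 for the interaction, where camera called 7, 10, 7, 6, 13 and 13.

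Among 179 named results, 130 kept their call in every alternative run for them. A change of direction was counted only where the main or the alternative test was passed. GPT2 on warming at ambient CO2 turned from -1.41 to 0.12 with dates as blocks, and its ratio of group means was 0.026 without control replicate 5. Leaving out 1 week ended further calls. For CO2 at 22 °C these were COR15A, GPT2, HSP101, MCM2, MCM5, PR1 and PRE1, for both PIF4, PR1 and YUC8, for CO2 at 30 °C ASN1, BCA1 and PR1, and for warming at ambient CO2 ASN1 and GPT2. For the interaction they were CAT2, CHS, CSLG2, DR4, GER3, GLDP2, LHCB1.4, MBF1C, PYD4, SARD4, SOT16 and THI2.2. Pairing by date changed only calls given beside the results, for the 179 and the lists. Other genes named were not compared. The correlation of warming and CO2 effects was -0.342 and -0.0941 with split and -0.186 with shared controls, and the cause was not tested. The chloroplast share on warming at elevated CO2 differed by 2.7 points as a median and 2.94 as a mean.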

Other observations

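In this part, the tests of the salicylic acid difference, of scaling, of levels across dates, and the splits for warming at ambient CO2 and for CO2 at 30 °C were chosen after results were seen, and the others before. Salicylic acid genes were lower at 30 °C than at 22 °C at ambient CO2. A few libraries with very high levels would leave the group medians equal, but these differed by -1.55 (permutation p = 1e-05, the smallest possible, in a family of 5), which excludes that account. Sampling date is excluded too, as the score was lower at 30 °C on 20 of 22 dates. Levels at 22 °C were in part shared by date: the scores of the control and the elevated CO2 group correlated at r = 0.502 across 22 dates (p = 0.0163, Spearman 0.543 with p = 0.0102), 0.407 without the 2 farthest dates and 0.455 within weeks. The score moved by 1.76 with CO2 at 22 °C (p = 0.0013, higher on 18 of 22 dates) and by -1.02 under both (p = 0.00049, lower on 19 of 21 dates). With CO2 at 30 °C it moved by 0.53, which did not pass as a median (p = 0.0655) but did paired by date (p = 0.011, higher on 15 of 21 dates) and as a mean (p = 0.0028).

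Salicylic acid and unfolded protein response scores rose and fell together among libraries at 22 °C. A scaling factor shared by all genes would give a positive correlation with light harvesting too, where it was -0.598, so this is excluded. Levels shared by date are excluded as the only cause, because differences between the groups within dates still correlated at r = 0.860 (p = 1e-05, the smallest possible, Spearman 0.852). A few libraries are excluded, with r = 0.820 or more without the 2 farthest. The source stays open, and no biological explanation was tested.

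No random split called as many genes as the real one in any comparison. For the interaction this cannot decide, as exchange over 4 groups also removed warming and CO2 effects. The others were fitted to only the groups compared. The real and highest other counts were 11106 and 588 for warming at ambient CO2, 6242 and 1 for CO2 at 22 °C, 9208 and 710 for both, 9230 and 1 for warming at elevated CO2, 2621 and 21 for CO2 at 30 °C and 1558 and 10 for the interaction. Exchange within dates gave highest other counts of 6939, 51, 1, 2146, 0 and 457 in 25 splits each. The split with 6939 genes kept or mirrored 86.4% of libraries as in the real grouping, and the one with 2146 kept 81.4%. The interaction split with 457 kept 22.99%, and whether it followed the warming groups was not tested.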
